A study of Homo sapiens with 5 samples.

How the data were processed

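The series holds RNA sequencing of human hepatic stellate cells, the liver cells that turn into matrix-producing myofibroblasts in fibrosis, grown on collagen I-coated polyacrylamide gels. Per the labels, 3 libraries came from cells on a stiff gel (25600 Pa) and 2 from cells on a soft gel (400 Pa), harvested after 2 days in medium with serum. The series title gives the stiff gel a rounder value than the sample labels, and the sample labels were followed. The design text names a stranded mRNA library kit and a HiSeq2500 instrument. The labels do not say whether the libraries came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

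The deposited table gives 1 FPKM value (fragments normalised to transcript length and to the number of mapped fragments) per gene symbol and library, as the authors' own normalization left it. The submitters' processing notes name the hg19 build, CASAVA 1.8.2, Trimmomatic 0.33, FastQC, Bowtie2 2.2.4.0, edgeR and DESeq2, with no role or order. The program that made the FPKM values, its annotation, its strand setting and any further scaling between libraries are not given in the sources used here. Many values are fractional estimates, not whole reads per length, so no count test was run. Antisense and overlapping genes, and near-identical copies such as HSPA1A and HSPA1B or the ribosomal protein genes and their pseudogenes, are uncertain for that reason.

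Of 26257 rows, 28 had gene names turned into dates by a spreadsheet; these held between 0.178% and 0.198% of the FPKM of a library and were left out. Of the 26229 others, 23695 matched a current gene symbol and 25131 a current or older one. Transcript lengths were taken by symbol from GENCODE release 29, using the principal transcripts and otherwise the longest. That annotation is on another build than the authors', so no coordinates are given. A length was found for 11539 of the tested genes (95.2%). XIST and Y-linked genes entered the tests and are not reported. The 13 mitochondrially encoded genes were not analysed here.

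Total counts per library are unknown. Relative depth was estimated from the steps that single reads leave in the FPKM of 2232 low genes (tolerance 0.03 on the log2 scale). Against stiff library 1 the other depths were 0.862 (stiff 2), 0.923 (stiff 3), 0.742 (soft 1) and 1.97 (soft 2). The steps were less clear than in whole-read tables, with 115 to 297 genes at the step against 22.8 to 49.0 by background. On simulated reads for 23657 genes the largest error of a depth was 2.1%. The simulated reads were whole and had 1 known length per gene. That error therefore does not carry over to the deposited values, whose depths are less certain.

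The comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with gel stiffness as the only term, a mean-variance trend in the variance prior and 3 residual degrees of freedom. A gene was tested when its mean FPKM over the 5 libraries was at least 1, which kept 12120 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Changes are stiff minus soft on the log2(FPKM + 1) scale, which understates the change of low genes. Folds are ratios of mean FPKM. Levels are mean ± SD with n = 3 on the stiff and n = 2 on the soft gel.

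Before the data were examined, 27 gene lists, the test design, the alternatives and the rule for named genes were fixed. Lists with at least 5 tested members (22 of 27) were tested with limma's camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way and compares the list with no other genes. The rule named the 12 largest changes per direction among called genes whose groups did not overlap, up to 4 genes per described list, and 22 genes on which stellate cell studies centre. Pseudogenes, small RNA genes and rows naming several genes were left out of it, and 2 genes that the rule takes are not reported here.

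The fit was tested on simulated data for the comparison of 3 stiff with 2 soft libraries over 12120 genes. In it 200 genes were changed by size and the 25 members of 1 list were raised by a log2 change of 0.5; 3 genes were in both sets and took the list's change. Of 50 genes drawn for each size, 42% were recovered at 1.25-fold, 70% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. Of 11898 unchanged genes, 11 were called (0.0925%). The simulated noise was independent between genes and few genes changed, whereas 57.8% of the tested genes were called in the data. These rates therefore do not carry over to the reported calls.

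The alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean FPKM of at least 5, 4 other scalings (upper quartile, trimmed mean, quantile and TPM), other variance priors, the replicate number as a block, each library left out, and a minimum log2 change of 1. Only stiff library 3 has the replicate number 3, so the block takes that library out of the gel effect. Effect sizes with the block therefore equal those without stiff library 3 and are not separate evidence. Settings added after the data were seen averaged stiff libraries 1 and 2 into 1 sample or removed a trend with transcript length from each library. Another left out small RNA rows. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for the descriptions and plots.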

Results

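Gene expression was measured in human hepatic stellate cells on stiff (25600 Pa, 3 libraries) and soft (400 Pa, 2 libraries) gels after 2 days. FPKM summed to 417983, 419922 and 385078 in the stiff libraries and to 385337 and 371923 in the soft ones. Between 11831 and 11964 genes reached 1 FPKM in a library. Soft library 2 was estimated to be 2.65 times as deep as soft library 1, and it listed the fewest genes at 0 (7233, against 8100 to 8342).

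Libraries of the same gel resembled each other more than libraries of different gels. Pearson correlations of log2(FPKM + 1) across genes were 0.957 to 0.963 within a gel and 0.914 to 0.921 between gels; genes are not independent replicates. The first principal component held 53.8% of the variance and separated the gels, and the next held 17.3%. Stiff libraries 1 and 2 were closer to each other than any other pair. For genes of 1000 to 3000 estimated reads, their spread was 1.44 times the variance that counting alone gives, against 6.44 times for stiff libraries 1 and 3 and 3.61 times for the soft pair. They were kept as separate samples, as labelled, although repeat preparations of 1 culture cannot be ruled out; averaging them gave 3141 higher and 2668 lower genes.

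The comparison asks how gel stiffness alters the transcriptome of these cells. On the stiff gel the cytokine genes IL11, IL6 and LIF and the growth factor genes PDGFA and VEGFA were higher, while HMOX1, the metalloprotease gene MMP3 and the basement membrane collagen genes COL4A1 and COL4A2 were lower. IL11, a cytokine of the interleukin 6 family, rose 28.8-fold, from 11.4 ± 0.365 to 327 ± 4.53 FPKM (log2 change 4.73 ± 0.04 SE, limma adjusted p = 5.22e-06). HMOX1, the heme-degrading enzyme heme oxygenase 1, fell 11.3-fold, from 1456 ± 58.3 to 129 ± 5.74 FPKM (log2 change -3.48 ± 0.06, adjusted p = 1.1e-05). Of 12120 genes, 3772 were higher and 3227 lower on the stiff gel, and 5121 did not pass. The groups did not overlap at 9002 genes (74.3%, where chance gives 20%).

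Many of these changes were small. Of the called genes, 5110 changed by less than 1.5-fold, while 471 rose and 188 fell by a log2 change of at least 1. Both counts use the log2(FPKM + 1) scale, which understates the change of low genes, and not ratios of mean FPKM. The balance of directions followed the scaling. Of the calls, 53.9% were higher on the stiff gel as deposited, 39.1% after upper-quartile scaling (2755 higher, 4286 lower), 41.1% after rescaling to TPM (2505 and 3595) and 43.5% after quantile normalization (3092 and 4009).

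**Figure D1:**
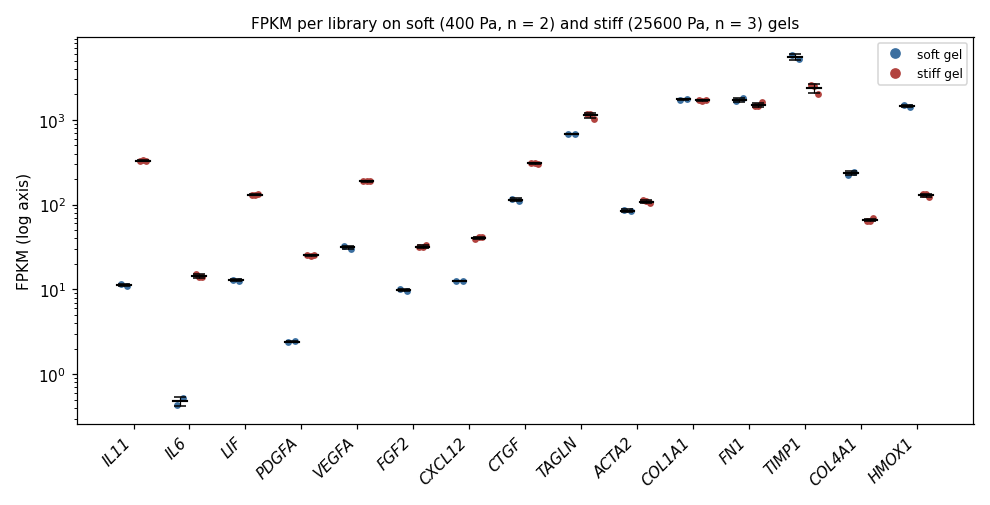
FPKM (log axis) of 15 named genes in each library on soft (blue, n = 2) and stiff (red, n = 3) gels; points are libraries, wide bars means and whiskers SD. IL11 sits near 11.4 FPKM on the soft and 327 FPKM on the stiff gel, whereas COL1A1 sits near 1753 and 1698 FPKM.

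Among the genes that rose most were further secreted factors and transcriptional regulators. IL6 rose 29.9-fold to 14.4 ± 0.762 FPKM, LIF 10.2-fold to 131 ± 0.676 and the growth factor gene FGF18 27.4-fold to 15.5 ± 0.392. The orphan nuclear receptor genes NR4A3 and NR4A1 rose 44.1-fold and 13.6-fold, the kinase gene SIK1 22.6-fold and the repressor gene HIC1 20.0-fold. The long noncoding RNA LINC00473 went from 0.222 to 23.5 FPKM, the tight junction gene CLDN4 from 1.13 to 53.5 FPKM and the hyaluronan synthase gene HAS2 from 1.14 to 22.9 FPKM. These genes had limma adjusted p-values of at most 3.14e-05.

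Genes that fell most included the protease inhibitor gene A2M (11.2-fold, to 3.01 ± 0.0611 FPKM), the oxidative stress gene OSGIN1 (9.18-fold, to 6.86 ± 0.400) and the secretogranin gene SCG2 (8.52-fold, to 10.3 ± 0.275). ACP5, a lysosomal acid phosphatase, went from 8.94 to 0.273 FPKM, and GPNMB, a glycoprotein of lysosomes and related organelles, from 18.4 to 2.40 FPKM. MGP, a matrix protein that inhibits calcification, fell 11.5-fold, and ZFP36, which promotes decay of AU-rich mRNAs, fell 6.43-fold. CRIP1, PNRC1, MMP11 and CCNG2, a cyclin gene, fell 9.81-fold, 8.17-fold, 7.37-fold and 7.93-fold. The limma adjusted p-values of these 11 genes and HMOX1 were at most 5.03e-05.

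Of 22 lists tested with camera, 14 passed the threshold, 8 higher and 6 lower on the stiff gel. With an estimated correlation 0 of the 22 passed, and 3 had an unadjusted p under 0.05. Camera's calls therefore hold only in the form with a preset correlation, and the adjusted p from the other form is given for each of the 14. Fry called 19, all but the interferon (fry adjusted p = 0.103), ribosomal protein (0.0587) and respiratory chain lists (0.0861). The last 2 had the highest estimated correlations, 0.935 and 0.833. Fry, but not camera, called the contractile, MRTF/SRF, p53, immediate early and epithelial lists higher and the integrin and quiescence lists lower. The size of the correlation alone does not explain why camera lost its calls. The cholesterol list, estimated at 0.00229 against the preset 0.01, also lost its call. The cell cycle list, estimated at 0.0112, went from a camera p of 5.40e-12 to 0.00645. With an estimated correlation, camera uses the 3 residual degrees of freedom of the fit, which leaves it little power.

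**Figure D2:**
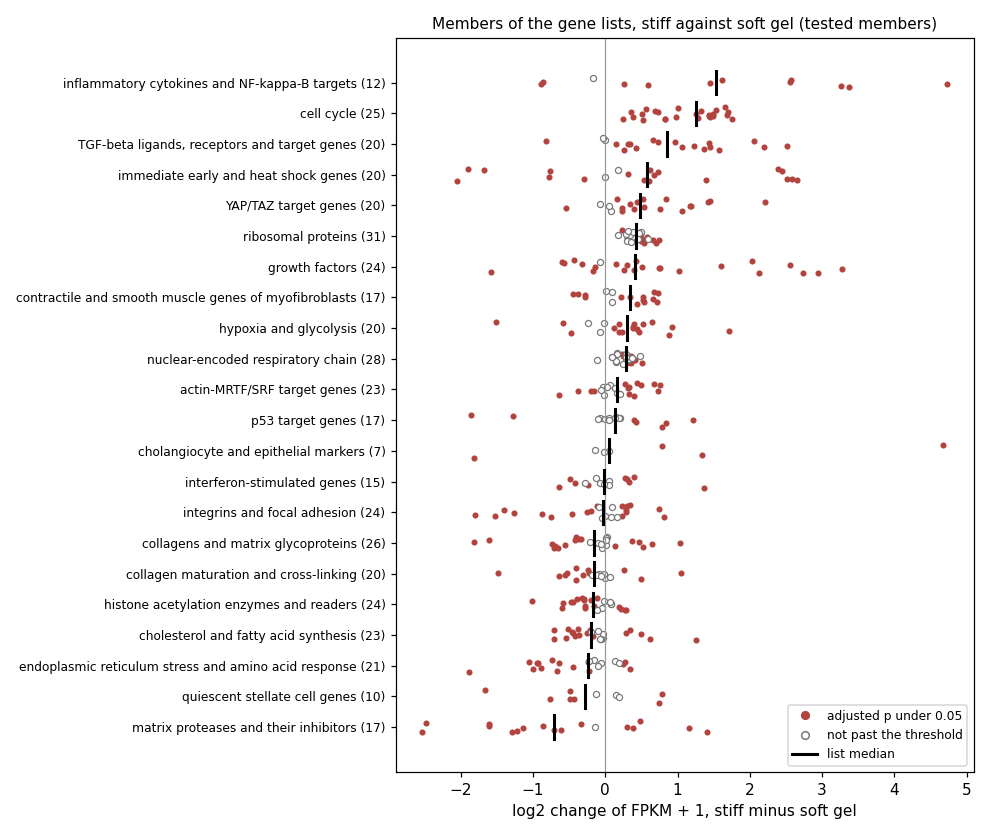
Log2 change of FPKM + 1 (stiff minus soft gel) of each tested member of the 22 lists; filled points passed an adjusted p of 0.05, open points did not, and bars are list medians, with the number of members in parentheses. All 25 cell cycle genes lie above 0, with a median of 1.26, and the protease list has the lowest median, -0.71.

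Cell cycle genes rose together. All 25 members were higher on the stiff gel, also when adjusted over the list alone (25), with a median log2 change of 1.26 (camera adjusted p = 1.19e-10). The adjusted p was 0.142 with an estimated correlation. The thymidylate synthase gene TYMS rose 3.48-fold to 79.5 ± 1.91 FPKM, and the mitotic genes CDC20, BIRC5 and CCNB2 rose 3.45-fold, 3.45-fold and 3.37-fold.

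Genes of TGF-beta signalling and of the mechanosensitive coactivators YAP and TAZ were mostly higher. In the TGF-beta list 17 of 20 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.85 (camera adjusted p = 5.38e-05, and adjusted p = 0.289 with an estimated correlation). JUNB rose 5.75-fold and the feedback regulator genes PMEPA1 and SKIL 5.11-fold and 4.71-fold. The ligand TGFB1 did not change detectably (116 ± 4.47 against 116 ± 13.6 FPKM, adjusted p = 0.979), and its fitted sign turned under all 4 other scalings. Of 20 YAP/TAZ targets 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 2.57e-04, and adjusted p = 0.289 with an estimated correlation). CTGF rose 2.69-fold, AMOTL2 2.84-fold, FJX1 5.23-fold and F3, tissue factor, 2.31-fold. CYR61 fell 1.47-fold (adjusted p = 2.55e-04), and ANKRD1 stayed below the filter (0.534 ± 0.174 against 0.402 ± 0.00412 FPKM).

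Growth factor and inflammatory genes held some of the largest changes. Of 24 growth factor genes 16 rose and 7 fell (16 and 7 adjusted over the list alone; median 0.41, camera adjusted p = 0.0170, adjusted p = 0.289 with an estimated correlation). PDGFA rose 10.5-fold to 25.4 ± 0.360 FPKM, HBEGF 7.18-fold, VEGFA 6.02-fold to 188 ± 1.24 FPKM and FGF2 3.25-fold. Of 12 inflammatory genes 9 rose and 2 fell (9 and 3 adjusted over the list alone; median 1.53, camera adjusted p = 0.00968, adjusted p = 0.289 with an estimated correlation). The chemokine genes CCL2 and CXCL12 rose 12.9-fold and 3.23-fold. Without the filter on low values the inflammatory list had a median of 0.14 and a camera adjusted p of 0.0748.

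Fibrillar collagens did not rise with stiffness in these libraries. COL1A1 (1698 ± 33.8 against 1753 ± 27.3 FPKM, adjusted p = 0.532), COL3A1 (219 ± 9.85 against 216 ± 11.6, adjusted p = 0.802) and the fibronectin gene FN1 (1502 ± 87.4 against 1732 ± 91.4, adjusted p = 0.0784) did not pass. FN1 was called lower after upper-quartile scaling (log2 change -0.32), in TPM (-0.31), without the variance trend (-0.21), with the length trend removed (-0.21), with the replicate block (-0.25) and without stiff library 3 (-0.25), and the fitted sign of COL3A1 turned under all 4 other scalings. COL1A2 was 1.15-fold lower (limma adjusted p = 0.0354). That call was lost without stiff library 1 (-0.20), stiff library 2 (-0.20), soft library 1 (-0.25) or soft library 2 (-0.17). It was lost with no filter (adjusted p = 0.239), after quantile normalization (0.284) and at a pseudocount of 0.01 (0.0528). It was also lost with a robust variance prior (0.0914), with stiff libraries 1 and 2 averaged (0.129) and with small RNA rows left out (0.0772). The basement membrane genes COL4A1 and COL4A2 fell 3.56-fold and 3.06-fold, LUM, lumican, fell 1.71-fold, and THBS1, thrombospondin 1, rose 2.06-fold. Of 26 collagen and glycoprotein genes 6 rose and 12 fell (6 and 12 adjusted over the list alone; median -0.15, camera adjusted p = 0.0342, adjusted p = 0.607 with an estimated correlation). The list's camera adjusted p was 0.0694 without stiff library 1, 0.0733 without stiff library 2, 0.0778 with no filter and 0.0619 after quantile normalization. It was 0.0621 with stiff libraries 1 and 2 averaged and 0.0545 with small RNA rows left out. The list also did not pass without soft library 2 (median -0.11), and its median was -0.26 in TPM.

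Among genes that process matrix more fell than rose. In the list for collagen maturation 10 of 20 fell and 3 rose (10 and 3 adjusted over the list alone; median -0.16, camera adjusted p = 0.0159, adjusted p = 0.289 with an estimated correlation). The median of this list was -0.27 after upper-quartile scaling, -0.32 after quantile normalization and -0.27 in TPM, with 14, 14 and 12 members lower. The prolyl hydroxylase subunit gene P4HA3 fell 3.00-fold, LOX, lysyl oxidase, fell 1.45-fold and LOXL1 rose 2.08-fold. Of 17 proteases and inhibitors 11 fell and 5 rose (11 and 5 adjusted over the list alone; median -0.71, camera adjusted p = 0.00968, adjusted p = 0.289 with an estimated correlation). Without the filter on low values the median of this protease list was -0.34. MMP3 fell 6.51-fold and the cathepsin gene CTSK 3.14-fold. TIMP1, an inhibitor of metalloproteases, fell 2.33-fold, from 5483 ± 435 to 2357 ± 285 FPKM.

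Contractile genes of myofibroblasts moved both ways, and the list did not pass camera, although fry called it higher (fry adjusted p = 1.27e-04). ACTA2, smooth muscle actin, rose 1.27-fold (108 ± 4.85 against 85.2 ± 2.50 FPKM, adjusted p = 0.00445) and TAGLN 1.65-fold. SMTN rose 1.68-fold and TPM1, tropomyosin 1, 1.60-fold, whereas CALD1, VCL, PALLD and TGFB1I1, named because they are the 4 that fell, were 1.21-fold to 1.36-fold lower. Of 17 members 10 rose and 4 fell (11 and 4 adjusted over the list alone; median 0.34), and camera gave an adjusted p of 0.10 (0.289 with an estimated correlation; 0.0184 at the preset one with no filter and 0.0368 in TPM). Of 23 targets of the actin-regulated factors MRTF and SRF 10 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.168), with FHL2 1.71-fold and CNN2 1.66-fold higher. Between 5 and 6 of these targets rose without stiff library 1 (6), stiff library 2 (6), soft library 1 (5) or soft library 2 (6), and 2 fell without stiff library 1, stiff library 2 or soft library 2. VIM, vimentin, rose 1.38-fold, a call lost without stiff library 1 (0.45), soft library 1 (0.46) or soft library 2 (0.46), with no filter (adjusted p = 0.142) and after quantile normalization (0.20). DES, desmin, stayed below the filter (0.976 ± 0.127 against 0.749 ± 0.166 FPKM).

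Integrin and quiescence genes moved both ways. Of 24 integrin and focal adhesion genes 8 rose and 10 fell (9 and 10 adjusted over the list alone; camera adjusted p = 0.371), and 4 rose after rescaling to TPM and 5 after quantile normalization. ITGA8, ITGA11, ITGA1 and ITGB5 fell 6.79-fold, 3.08-fold, 2.84-fold and 2.44-fold. Of 10 genes of quiescent stellate cells 2 rose and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.182); without the filter on low values 4 rose and 6 fell. Cytoglobin, CYGB, fell 3.40-fold and the lipid droplet gene PLIN2 1.72-fold, whereas PPARG rose 1.75-fold. The receptor PDGFRB did not pass (adjusted p = 0.0842), but was called lower after upper-quartile (log2 change -0.23), trimmed-mean (-0.16) and quantile scaling (-0.26), with the length trend removed (-0.12), with the replicate block (-0.15) and without stiff library 3 (-0.15).

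In 3 lists of stress, lipid and chromatin genes more members fell than rose. Of 21 genes of endoplasmic reticulum stress and the amino acid response 12 fell and 3 rose (12 and 3 adjusted over the list alone; median -0.24, camera adjusted p = 0.00331, adjusted p = 0.289 with an estimated correlation). The members that rose numbered 1 after quantile normalization or rescaling to TPM. DDIT3 fell 3.90-fold, asparagine synthetase, ASNS, 2.11-fold and ATF4 1.94-fold. Of 23 genes of cholesterol and fatty acid synthesis 12 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.20, camera adjusted p = 0.0227, adjusted p = 0.289 with an estimated correlation). HMGCS1 fell 1.67-fold, and INSIG1, which restrains sterol synthesis, rose 2.41-fold; 3 members rose after rescaling to TPM. Of 24 histone acetylation enzymes and readers 14 fell and 4 rose (15 and 4 adjusted over the list alone; median -0.17, camera adjusted p = 0.0170, adjusted p = 0.289 with an estimated correlation). EP300, the acetyltransferase p300, fell 1.28-fold (9.05 ± 0.460 against 11.6 ± 0.0968 FPKM, adjusted p = 0.00402) and BRD2 fell 1.51-fold. The count of histone list members that rose was 0 after upper-quartile scaling or rescaling to TPM and 1 without soft library 1.

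In the metabolic and ribosomal lists more members rose than fell. Of 20 hypoxia and glycolysis genes 14 rose and 3 fell (14 and 3 adjusted over the list alone; median 0.31, camera adjusted p = 0.0342, adjusted p = 0.358 with an estimated correlation). PFKFB3 rose 3.40-fold and LDHA 1.90-fold, while ADM fell 2.97-fold. That list lost its call at a mean FPKM of at least 5 (camera adjusted p = 0.0872) and after quantile normalization (median 0.11, adjusted p = 0.0823). The list also lost its call with stiff libraries 1 and 2 averaged (camera adjusted p = 0.0621) and with small RNA rows left out (0.0624). Of its members, 9 rose without stiff library 1, soft library 1 or soft library 2. With a library left out it passed only without stiff library 3; its camera adjusted p was 0.0694 without stiff library 1, 0.0554 without stiff library 2, 0.0542 without soft library 1 and 0.0595 without soft library 2. Of 31 ribosomal protein genes 18 rose (19 adjusted over the list alone; median 0.43, camera adjusted p = 0.00128, adjusted p = 0.607 with an estimated correlation). RPS2 rose 1.59-fold and RPL8 1.63-fold, the latter a call lost without soft library 2 (log2 change 0.62, adjusted p = 0.0737). Of 28 nuclear-encoded respiratory chain genes 10 rose (9 adjusted over the list alone; median 0.29, camera adjusted p = 0.0145, adjusted p = 0.651 with an estimated correlation), and camera did not pass without soft library 2 (adjusted p = 0.0595) or with the length trend removed (median 0.12, adjusted p = 0.0847).

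These 2 groups of short transcripts differed between the stiff libraries. Relative to the mean of the soft libraries, the ribosomal protein median was 0.51, 0.53 and 0.20 in stiff libraries 1, 2 and 3, and the respiratory chain median was 0.38, 0.37 and 0.07. Of the ribosomal protein genes, 30 rose without stiff library 3, 5 without stiff library 1, 6 without stiff library 2, 5 without soft library 1, 2 without soft library 2 and 29 with the replicate block. Of the respiratory chain genes, 25 rose without stiff library 3 or with the block, 5 without stiff library 2, 4 without soft library 1 and 4 without soft library 2. Among the 1154 genes with the shortest transcripts, the median was 0.24 and 0.23 in stiff libraries 1 and 2 and 0 in stiff library 3.

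**Figure D3:**
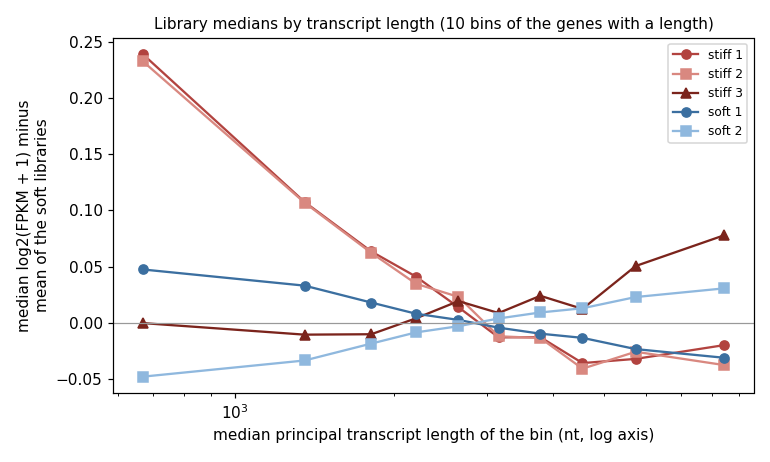
Median log2(FPKM + 1) of each library minus the mean of the soft libraries (vertical axis) over 10 bins of the genes ordered by principal transcript length (horizontal axis, nt, log scale). Stiff libraries 1 and 2 reach 0.24 and 0.23 for the shortest genes, where stiff library 3 is at 0 and the soft libraries at 0.05 and -0.05.

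Immediate early and heat shock genes went apart. Of 20 members 12 rose and 6 fell (12 and 6 adjusted over the list alone; median 0.57, camera adjusted p = 0.103). Camera passed after upper-quartile scaling (adjusted p = 0.0260), quantile normalization (0.0454), rescaling to TPM and with no filter (0.0343), and with an estimated correlation the adjusted p was 0.410. EGR2 and EGR3 rose 11.7-fold and 10.6-fold and MYC 5.94-fold. Of 17 p53 targets 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.232), with BBC3 4.90-fold lower and PLK3 2.42-fold higher. Of 15 interferon-stimulated genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.696), with IFIT1 4.13-fold higher; without soft library 1, 3 rose and 5 fell, and at a mean FPKM of at least 5, 1 rose and 2 fell. The interferon list's median (-0.01) and mean (0.03) differ in sign, as do camera (lower) and fry (higher).

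Hepatocyte markers and most endothelial and leukocyte markers were low, whereas some epithelial and portal fibroblast markers were well expressed. The 14 hepatocyte markers stayed at or below 0.703 FPKM in every library. Of 12 endothelial markers only TEK was tested (4.99 ± 0.319 against 5.70 ± 0.209 FPKM, adjusted p = 0.0620; called lower without stiff library 3 or with the replicate block, at -0.20, and after upper-quartile, trimmed-mean and quantile scaling, at -0.26, -0.20 and -0.21). Of 16 macrophage and leukocyte markers only CD68, which many cell types express, was tested. It was 1.14-fold lower (adjusted p = 0.0333), a call lost without stiff library 1 (-0.19), stiff library 2 (-0.20), stiff library 3 (-0.17) or soft library 1 (-0.12), and with the replicate block (-0.17). Of 7 epithelial genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.431), with KRT19 2.67-fold higher (32.6 ± 2.41 FPKM) and SPP1 5.31-fold lower beside CLDN4. The 2 measured portal fibroblast markers moved apart, THY1 1.42-fold higher (131 ± 5.37 against 92.3 ± 0.999 FPKM) and FBLN2 1.51-fold lower (1 and 1 adjusted over the list alone).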

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

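The settings that averaged stiff libraries 1 and 2, removed the length trend or left out small RNA rows were chosen after the results were seen. Every gene called both in the reported fit and under a given alternative kept its sign, though requiring both calls favours that. Of the 122 named genes tested, 107 kept call and direction under all settings but the size threshold, which ended 45 calls. Most were named for large changes or calls, so this share does not describe all calls. Of the 6999 calls, 5577 held without stiff library 1, 5556 without stiff library 2 and 6650 without stiff library 3. Counts of higher genes ranged from 2783 to 4111 and of lower genes from 2292 to 3363 over the libraries left out. They moved by over 1.5 times to 2059 lower genes at a mean FPKM of at least 5 (fewer genes tested) and to 2505 higher genes in TPM. In TPM the median log2 change of all tested genes moved from 0.029 to -0.069, and other causes were not tested. With a log2 change of at least 1 the counts were 471 and 188. With stiff libraries 1 and 2 averaged, 3141 genes were higher and 2668 lower (5773 of the calls shared). The count of lists called, 14, was 11 to 14 with a library left out and 0 with an estimated correlation. The excess of within-gel over between-gel correlation was 0.0473 at both lower pseudocounts, 0.0183 with no filter, 0.0617 at a mean FPKM of at least 5, 0.0454 in TPM and 0.0497 by Spearman; the cause was not tested.

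Of the named genes, 2 that did not pass changed direction, and so did 2 lists that did not pass. COL3A1 was at -0.092 after upper-quartile scaling, -0.019 after trimmed-mean scaling, -0.118 after quantile normalization, -0.086 in TPM, -0.017 with the block, and -0.035 to 0.074 with a library left out. TGFB1 was at -0.108, -0.035, -0.132 and -0.102 under those scalings, -0.011 with stiff libraries 1 and 2 averaged, -0.001 with the length trend removed, and -0.117 to 0.122 with a library left out. The interferon list turned in camera's direction with no filter (median -0.005) and in fry's (median -0.015). Its median turned to 0.096 without stiff library 3 and with the block, and to 0.02 without soft library 1. The epithelial list's median, 0.055, was -0.003 after upper-quartile scaling. The cause was not tested.

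Replicate numbers 1 and 2 occur in both groups, and deviations of same-numbered libraries correlated at 0.031 and -0.055. These values cannot settle whether the numbers pair the samples, because the deviations of the 2 soft libraries mirror each other. With the replicate block 3822 genes were higher and 3015 lower. Leaving out a soft library leaves 1, which is assumed to vary like the stiff ones. The lower depth of soft library 1 limits what its low genes can show, and true read numbers are unknown. The planned count tests were not run because the table holds no counts.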

Other observations

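The 4 lists and all tests in this part were chosen after the results were seen. Genes known as targets of NRF2, the regulator of antioxidant defence, were mostly lower on the stiff gel: 20 of 24 fell and 2 rose (median log2 change -0.58). Without HMOX1 and OSGIN1, which prompted the list, 18 of 22 fell and 2 rose (median -0.54). SQSTM1, the autophagy receptor p62, fell 2.97-fold, the cystine transporter gene SLC7A11 2.57-fold, GCLM, a subunit of the glutathione-synthesis enzyme, 2.15-fold and NQO1 1.74-fold. Lysosomal genes fell in 28 of 29 cases and rose in 0 (median -0.67), or in 26 of 27 without ACP5 and GPNMB (median -0.63), among them the cathepsin genes CTSD (1.95-fold) and CTSF (1.92-fold) and PSAP, prosaposin (1.82-fold). With an estimated correlation the camera p was 0.0352 for the NRF2 list and 0.0461 for the lysosome list. The adjusted p over the 4 lists was 0.0534 for both. Without the genes that prompted each list, that camera p was 0.0393 and 0.0435. The adjustment covers only the 4 lists picked after the results were seen. It is therefore not comparable with the adjustment over the 22 fixed lists, and these p-values are no independent support.

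Genes known to respond to cAMP and CREB rose in 18 of 18 tested cases (median 1.65). Without the filter on low values 18 of 20 rose and 1 fell (median 1.37). GEM rose 7.21-fold, FOSB 5.40-fold, RGS2 4.15-fold and PDE4D 5.35-fold, and 14 of 14 rose when the genes already named for their size were set aside (median 1.14). Ribosome biogenesis genes rose in 23 of 30 cases and fell in 1 (median 0.45), with RRS1 2.60-fold and URB2 2.28-fold higher. The medians of that list were 0.45, 0.44 and 0.50 in stiff libraries 1, 2 and 3. With an estimated correlation the camera p was 0.0221 for the cAMP and CREB list and 0.0534 for ribosome biogenesis. The adjusted p was 0.0534 for both. Without the genes already named for their size the cAMP and CREB list had a camera p of 0.0236. The same limits apply to these p-values.

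Single genes outside the rule also stood out, chosen after their values were seen. The clock gene NR1D1 went from 24.9 to 4.41 FPKM, while NFIL3 went from 15.1 to 71.5 FPKM. The transcription factor genes SOX4 and SOX9 went from 9.34 to 82.4 and from 5.29 to 42.5 FPKM.

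The rise of ribosomal protein and respiratory chain genes was set against a transcript-length trend that differs between libraries. The ribosomal protein median exceeded that of 10000 lists of other genes matched on length and expression by 0.34 (matched range -0.08 to 0.22). The matched genes were drawn independently, whereas ribosomal protein genes move together (estimated correlation 0.935). The range is therefore too narrow to decide against the trend. With the length trend removed per library, the ribosomal protein median was 0.29. For the respiratory chain the excess was 0.12 (list median 0.28, matched range 0.01 to 0.27), smaller than the matched median of 0.16, and its camera adjusted p was 0.0847 once the trend was removed. For these genes the gel and the length trend cannot be told apart, because the excess is small, the longest transcripts in place of the principal ones put the list within the matched range (-0.01 to 0.33), and stiff library 3 lies close to the soft libraries. A response to stiffness remains open for both groups.

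For the lower NRF2 target and lysosomal genes stiffness is the only labelled difference, and no mechanism was tested. The list medians differed from those of matched lists by -0.66 and -0.74. The matched genes were drawn independently, whereas list members may move together (estimated correlations 0.0711 and 0.191), so the matched ranges are too narrow. With the length trend removed per library the list medians were -0.599 and -0.695, which argues against a length trend as the whole cause. All tested members, including those that prompted each list, entered these comparisons and the next ones. A wrong scale of whole libraries would move other genes as much, yet the list medians differed from the median of the other tested genes by -0.61 and -0.70. These gaps as deposited argue against such a scale as the whole cause. Upper-quartile, trimmed-mean and TPM scaling use a single factor per library. They can shift the gaps only through the pseudocount, so they add no support. Quantile normalization gave -0.63 and -0.76. RNA of macrophages in the soft cultures is argued against by the highest of 15 markers other than CD68, CD14, at 0.920 FPKM in a soft library, where lysosomal genes were higher by a median of 20.8 FPKM. The labels name no sort or gate, and differences in handling between the gels were not tested.

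Higher cAMP and CREB targets may reflect that pathway or a wider immediate early response. The 17 members with a length had a median of 1.39, an excess of 1.37 over matched lists. The matched genes were drawn independently, whereas list members may move together (estimated correlation 0.106). With the length trend removed per library the median was 1.36, which argues against a length trend as a whole cause. The genes already named for their size were included in these comparisons and the next ones. A wrong scale of whole libraries is argued against, as a whole cause, by an excess of 1.62 over the other tested genes as deposited. Scalings by a single factor per library shift that excess only through the pseudocount and add no support. Quantile normalization gave 1.71. The activity of the pathway was not measured. Immediate early genes outside the list also rose, with a median of 0.64 (10 of 12 higher and 1 lower), so a wider response remains open. The 95% bootstrap interval of that median was 0.43 to 2.48. It resamples the 12 genes with the libraries fixed, so it shows the spread among genes and not between samples. Heat shock genes did not share it: 5 of 6 fell and 0 rose (median -0.77).

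In the 10 splits of the 5 libraries into 3 and 2, 1 split, the real one, gave 6999 called genes, and the highest of the other splits gave 6. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes stiff and soft libraries within a group, so the difference between the gels enters its residual spread. Few calls then follow whether that difference is biological or technical, and the contrast cannot tell these apart. The split of stiff libraries 1 and 2 from the other 3 had 1327 genes at an unadjusted p under 0.05, against 22 to 245 in the other 8 wrong splits.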
